A study of Mus musculus with 24 samples.

How the data were processed

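The series measured gene expression in pancreatic tumors of KPC mice, a model in which mutant Kras and Trp53 are switched on in the pancreas and ductal adenocarcinoma follows. Mice received polyclonal human IgG or FG-3019, a human monoclonal antibody against connective tissue growth factor (CTGF), each at 30 mg/kg, with or without gemcitabine at 100 mg/kg, and tumors were taken on day 9. There were 24 arrays, 1 per mouse, with 7 in the IgG arm, 5 in the FG-3019 arm, 6 in the IgG plus gemcitabine arm and 6 in the FG-3019 plus gemcitabine arm. Groups, sex and mouse number came from the labels, and each mouse gave 1 array, so replicates are separate animals.

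The deposited table held 22690 probe sets of an Affymetrix 430A 2.0 array. Per the series' design text in the labels, the authors processed the scanner files with GC-RMA and rescaled each gene by its median in GeneSpring GX 7.3.1. The deposited values were linear ratios: for all 22690 probe sets the median of the 7 IgG arrays was 1 within a tolerance of 1e-06, so each value is a ratio to the IgG median, although the labels do not say which arrays the median was taken over. The lowest value was 0.01, reached by 9 values in 6 probe sets. The ratios carry no absolute level, so signal over background is unknown, no filter on dim probe sets was possible, and the number of arrays limits the precision. The genome build behind the array annotation is not given in the sources used here, and no coordinates are printed.

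Of the probe sets, 20380 named 1 gene, 691 named several, 1555 had no gene named and 64 were controls. Symbols were checked by Entrez number against a RefSeq gene table of GRCm38.p6, in which 29 numbers were missing and 0 symbols needed updating. Probe sets with several genes were not used. For each of 12393 genes the probe set with the largest interquartile range over all 24 arrays stood for the gene.

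Values were converted to log2 with no pseudocount. A linear model with the 4 arms and sex was fitted to all 24 arrays with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with robust empirical Bayes moderation, 19 residual degrees of freedom and a median of 1.89 prior degrees of freedom. Sex was a covariate because all 5 FG-3019 mice were female. The 8 contrasts were 5 comparisons of 2 arms, the antibody and gemcitabine effects averaged over the other treatment, and their interaction. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and 0.05 was the threshold. Adjusted p-values of genes below are limma's unless another test is named.

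Before the data were examined, 34 gene lists with 729 genes were fixed, of which 642 genes were measured. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with the correlation estimated from the data and the rotation test fry as alternatives. These alternatives were run on the main fit alone, so their calls were not checked with arrays left out. The genes named were fixed by a rule at the same time: in a comparison of 2 arms the 10 largest rises and 10 largest falls past the threshold, with smallest-p genes filling a direction up to 5; in the averages and the interaction 5 and 5, filled up to 3; Ctgf (named Ccn2 in the annotation) and Xiap everywhere; and up to 4 members with the smallest p of a described list. Xist and Y-linked genes were left out of the top genes.

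The fit was tested on 5 simulated data sets of 12393 genes with the real standard deviations and 200 changed genes each. For FG-3019 plus gemcitabine against IgG plus gemcitabine it recovered 67.2% of the genes changed 2-fold and 92.6% of those changed 4-fold, and 4.6% of its calls were wrong. Simulated genes were independent, so this test does not cover correlated genes in lists.

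Alternatives set before the data were examined were the fit without sex, females alone, the compared arms alone, a block for replicate number, quantile normalization, arrays centred on their median, the mean of all probe sets of a gene, leaving out probe sets that match several transcripts, the more variable genes alone, a floor on low values, moderation without robustness, array weights, mouse number as a covariate, leaving out 4 arrays out of number order, and leaving out each array in turn. Chosen after seeing the data were removal of a trend with gene span and leaving out doubted arrays. Control comparisons used permutation tests with 100000 resamples, or exact tests within an antibody comparison, all two-sided. Figures and table handling used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.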

Results

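Tumor RNA of 24 KPC mice was hybridized to 24 arrays, 7 from mice given IgG, 5 given FG-3019, 6 given IgG plus gemcitabine and 6 given FG-3019 plus gemcitabine. The 2-by-2 layout addresses what blocking CTGF changes in these tumors, what gemcitabine changes, and whether the effects of both depend on each other. Values are log2 ratios to the median of the IgG arrays, and 12393 genes were tested in each comparison. The number of arrays limits the precision.

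The array controls and the mice were not spread evenly over the arms. Poly-A spike-ins, bacterial RNAs added to each sample before labelling, averaged 0.64 lower on the log2 scale on FG-3019 arrays (log2 difference −0.64, permutation p = 2e-05 within gemcitabine strata). The difference was −0.57 without gemcitabine (exact p = 0.0051) and −0.70 with it (exact p = 0.0043). Hybridization spike-ins, added after labelling, differed by −0.26 (permutation p = 3e-05), and by −0.16 without IgG plus gemcitabine replicate 1, where they were highest. The Gapdh 3′ to 5′ ratio, a sign of RNA integrity, differed by −0.11 (permutation p = 0.0051, adjusted p = 0.0086 over 5 control measures), but by −0.05 without gemcitabine (exact p = 0.184). The same ratio of Actb differed by −0.05 and did not pass (permutation p = 0.109). Mouse numbers averaged 1737 higher in the FG-3019 arms than in the IgG arms. Both with and without gemcitabine, every FG-3019 mouse had a higher number than every IgG mouse. Within a gemcitabine stratum the antibodies thus shared no range of mouse numbers. Fits with mouse number as a covariate rest on slopes within arms and separate number from antibody poorly. All 5 mice of the FG-3019 arm were female. No processing batch is named in the labels. A batch, or a step between cohorts, that followed the antibody cannot be told apart from the antibody in the comparisons between antibodies below.

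Labelled sex was set against sex-linked genes. Xist, the RNA that silences an X chromosome in female cells, averaged 4.00 ± 2.69 (SD, n = 15) in females and −2.71 ± 3.30 (SD, 9 males) in males, and the difference was 6.71 (permutation p = 1e-04). The mean of 3 Y-linked genes was at most −0.01 in females and at least 2.19 in males. Xist was out of place on 2 arrays, at −5.29 in IgG replicate 7, labelled female, and at 3.90 in IgG plus gemcitabine replicate 4, labelled male. Both were kept as labelled.

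FG-3019 against IgG asks what the antibody changed without chemotherapy. Ccn2, which encodes the antibody's target CTGF, had a log2 change of −0.10 (SE 0.25, adjusted p = 1.00). No gene rose and 12 fell. Birc6, a large inhibitor of apoptosis with ubiquitin ligase activity, had the largest fall, with a log2 change of −1.80 (SE 0.26, adjusted p = 0.0030), a 3.48-fold lower level. Other falls were in the ubiquitin ligases Ube3a (−1.24, SE 0.17) and Trip12 (−1.10, SE 0.18), in Sos1, an exchange factor that activates Ras (−1.27, SE 0.23), and in Gtf2a1, a general transcription factor subunit (−0.94, SE 0.17). Suco (−1.36), Pibf1 (−1.34), Tmem33 (−1.27), Xpr1, a phosphate exporter (−1.18), and Secisbp2l (−1.16) fell as well. Xiap, a caspase inhibitor, had a log2 change of −1.02 (SE 0.25) and did not pass (adjusted p = 0.176). The smallest p among higher values belonged to Emc6 (0.48), Asns, asparagine synthetase (1.01), Cfap298 (0.60), Tpra1 (0.51) and Snrpg (0.56), none of which passed.

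Among the fixed lists, 19 shifted in this comparison by camera. In no comparison was the count of called lists beyond chance, since 6 to 75 of 100 splits of the same arrays gave as many. All 29 mitosis genes were higher, with a median of 0.55, and 0 passed alone, Aurkb at 0.77 and Mad2l1 at 0.61 having the smallest p. DNA replication genes had a median of 0.38 with 29 of 31 higher and 0 past the threshold, Pold1 at 0.73 among them. Of 22 collagens 21 were lower, with a median of −0.48 and 0 past the threshold, Col12a1 at −0.59 and Col6a3 at −0.80. Matrix glycoproteins and crosslinkers had a median of −0.37, and 1 of 28, the laminin chain Lamc1 (−1.21), passed when adjusted over the list alone (adjusted p = 0.0043), against 0 over all genes. Ductal epithelial markers had a median of 0.51, with Krt19 at 0.58 and Muc1 at 0.78. With an estimated correlation each of these 5 lists had an adjusted p = 0.517 and none was called. Inhibitors of apoptosis had a median of −0.09, with 2 of 16 past the threshold adjusted over the list alone, Birc6 and Xiap, and an adjusted p = 0.218 with an estimated correlation. Without IgG replicate 2 the medians were −0.27 for collagens and −0.17 for matrix glycoproteins, and the ductal call ended at 0.33. Without FG-3019 replicate 5 they were −0.28 and −0.22, and without IgG replicate 4 the collagen median was −0.29. The ductal call also ended without FG-3019 replicate 4, at 0.31. The median of apoptosis inhibitors was −0.19 without IgG replicate 3, −0.14 without IgG replicate 7, −0.03 without FG-3019 replicate 1 and −0.025 without IgG replicate 4. Without sex in the fit collagens (−0.12), matrix glycoproteins (0.02) and ductal markers (0.19) were not called, whereas mitosis (0.31) and DNA replication genes (0.24) were. In females alone collagens (−0.62) and matrix glycoproteins (−0.51) were called, and ductal markers (0.32) and apoptosis inhibitors (−0.08) were not. With mouse number as a covariate collagens, matrix glycoproteins and apoptosis inhibitors were not called.

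Markers of other cell types were called in the same comparison. B and plasma cells (0.71), adipocytes (0.53), neutrophils (0.48), muscle (0.20) and T and NK cells (0.14) were higher and islet genes (−0.58) lower as medians, with an adjusted p of 0.517 or more with an estimated correlation. Without FG-3019 replicate 1 the adipocyte (0.24), neutrophil (0.22) and muscle (0.05) calls ended, and without FG-3019 replicate 2 that of B and plasma cells (0.14). The neutrophil call also ended without IgG replicate 3 (0.31) or 5 (0.40), FG-3019 replicate 5 (0.33) or IgG plus gemcitabine replicate 3 (0.39). The islet call ended without IgG replicate 2 (−0.25) or 4 (−0.21) or FG-3019 replicate 5 (−0.27), and its median was −1.13 without IgG replicate 3, −1.31 without IgG replicate 7 and −1.095 without FG-3019 replicate 3. Without FG-3019 replicate 5 the median of B and plasma cells was 0.46. The T and NK cell call ended for 12 of 24 arrays left out, with medians from 0.055 without FG-3019 replicate 2 to 0.26 without IgG replicate 2. In females alone only the islet list was called of these, and without sex in the fit adipocytes, neutrophils and islet genes were not. With mouse number as a covariate adipocytes (0.24), islet genes (−0.17) and muscle (0.165) were not called.

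The count of 12 fell to 5 without FG-3019 replicate 2 or 3, to 6 without FG-3019 replicate 5, rose to 21 without IgG replicate 3, and was 0 with mouse number as a covariate or with only the compared arms in the fit. It was 1 in females alone and 2 with the mean of all probe sets of a gene. Of the 10 called genes named, 4 passed whichever array was left out, Birc6, Suco, Pibf1 and Ube3a, and Xpr1 did not pass without sex in the fit.

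FG-3019 plus gemcitabine against IgG plus gemcitabine asks the same of mice under chemotherapy and uses none of the arrays of the first comparison. Here 10 genes rose and 157 fell. Tff2, a secreted trefoil peptide of mucous epithelium, rose by 3.70 (SE 0.91, adjusted p = 0.042), a 13.0-fold higher level. Cyp2j5, a cytochrome P450 (2.09), Chpt1, a choline phosphotransferase (1.24), Alad, an enzyme of heme synthesis (1.22), Frmd4b (1.04), Cyb5b (0.90), Zfp672 (0.78), Lrrc51 (0.71), Sypl (0.66) and Osbpl10 (0.60) also rose. The largest falls were in the kinase gene Lrrk1 (−2.38, SE 0.38) and the calcium channel subunit Cacna2d1 (−2.31, SE 0.45). Hdlbp, an RNA-binding protein, fell by 1.76 (SE 0.21), and Utrn, which links the cytoskeleton to the membrane, by 1.70 (SE 0.22). The translation initiation factor subunit Eif3c fell by 1.68 (SE 0.18, adjusted p = 6.6e-05). Hif1a, the oxygen-regulated transcription factor subunit, fell by 1.61 (SE 0.30), and Gatad2b (−1.63), Thrap3 (−1.63), Supt16 (−1.60) and Dcbld2 (−1.56) fell too. Xiap fell by 1.08 (SE 0.24, adjusted p = 0.021), a 2.12-fold lower level, and Ccn2 was at −0.14 (SE 0.24, adjusted p = 0.837).

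By camera 15 lists shifted. Of 22 ductal epithelial markers 18 were higher, with a median of 0.48, and Tff2 alone passed over all genes, with Agr2 at 3.03. Matrix proteases and their inhibitors were lower in 21 of 23 genes, with a median of −0.31. Mmp14, a membrane-bound collagenase, fell by 1.16 (adjusted p = 0.039), and Timp2 (−1.15) passed adjusted over the list alone. Genes of epithelial to mesenchymal transition had a median of −0.60, with 5 of 16 past the threshold adjusted over the list alone, among them Snai2 (−0.86) and Zeb2 (−1.10), and 0 over all genes. Markers of normal pancreas were higher, islet genes with a median of 1.74 and 7 of 16 past the threshold adjusted over the list alone, Chgb (3.97) and Chga (2.68) among them, and acinar genes with a median of 1.94 and 0 past it, Gp2 at 3.80. Neither Chgb nor Chga passed over all genes. Each of these 5 lists had an adjusted p = 0.614 with an estimated correlation, so no call held. Without IgG plus gemcitabine replicate 3 the ductal median was 0.22 and the list was not called by camera. Matrix proteases (−0.22) and mesenchymal genes (−0.305) were not called without sex in the fit, nor in females alone or with mouse number as a covariate, and with the last the acinar median was 0.305 and not called. Also called were erythroid genes (0.93), B and plasma cells (0.91) and MHC class II (0.52), each with an adjusted p = 0.614 with an estimated correlation and none of them in females alone. Erythroid genes were not called without sex in the fit (0.63) or with mouse number as a covariate (0.94) either. The erythroid median was −0.03 without FG-3019 plus gemcitabine replicate 4, and the erythroid call ended there and without IgG plus gemcitabine replicate 4 (0.86), 5 (0.86) or 6 (0.95). That of B and plasma cells was 0.36 without FG-3019 plus gemcitabine replicate 4 and 0.445 without replicate 5, where MHC class II had 0.33.

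The count of 167 was 75 without FG-3019 plus gemcitabine replicate 5 and 100 without IgG plus gemcitabine replicate 3. It was 10 with mouse number as a covariate, 35 in females alone, 34 with the mean of all probe sets of a gene and 89 after quantile normalization. Of the 22 called genes named, 12 passed whichever array was left out, Chpt1, Frmd4b and the 10 largest falls, whereas Tff2 passed in 10 of 24 cases and Mmp14 in 14. Xiap did not pass without IgG plus gemcitabine replicate 2 or FG-3019 plus gemcitabine replicate 4 or 5. Tff2, Cyp2j5, Alad, Sypl, Osbpl10, Cacna2d1 and Mmp14 did not pass without sex in the fit.

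The antibody effect averaged over gemcitabine had 9 genes higher and 152 lower. Birc6 fell by 1.62 (SE 0.19, adjusted p = 0.00015), Cacna2d1 by 1.64 (SE 0.34), Hif1a by 1.44 (SE 0.23), Lrrk1 by 1.34 (SE 0.29) and Top2b, a DNA topoisomerase, by 1.27 (SE 0.23). Alad (1.05), Mansc1 (1.04), Cyb5b (0.68), Frmd4b (0.55) and Lrrc51 (0.51) rose. Xiap fell by 1.05 (SE 0.18, adjusted p = 0.0030), a 2.07-fold lower level. It passed whichever array was left out, as did Alad, Birc6, Hif1a and Top2b, 5 of 14 called genes named. Xiap had 6 probe sets, with log2 changes from −1.12 (SE 0.20) to −0.02 (SE 0.08). Its fall did not pass in females alone (−0.83, adjusted p = 0.145), with the mean of its probe sets (−0.62, adjusted p = 0.077) or with mouse number as a covariate (−0.56, adjusted p = 0.760), and passed in the other 37 of 40 alternatives, over which the adjusted p ran from 0.0016 to 0.760. Bcl2l2, a relative of Bcl2, was at −0.60 and passed adjusted over the list of apoptosis inhibitors alone. Ccn2 was at −0.12 (SE 0.18, adjusted p = 0.841). The 5 measured CCN family genes had a median of −0.12 and a mean of 0.01, with Ccn5 at 0.75, Ccn4 at −0.33 and Ccn1 at −0.26, and none passed. The mean of that list thus differed in sign from its median and from camera's direction, which was lower.

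**Figure D1:**
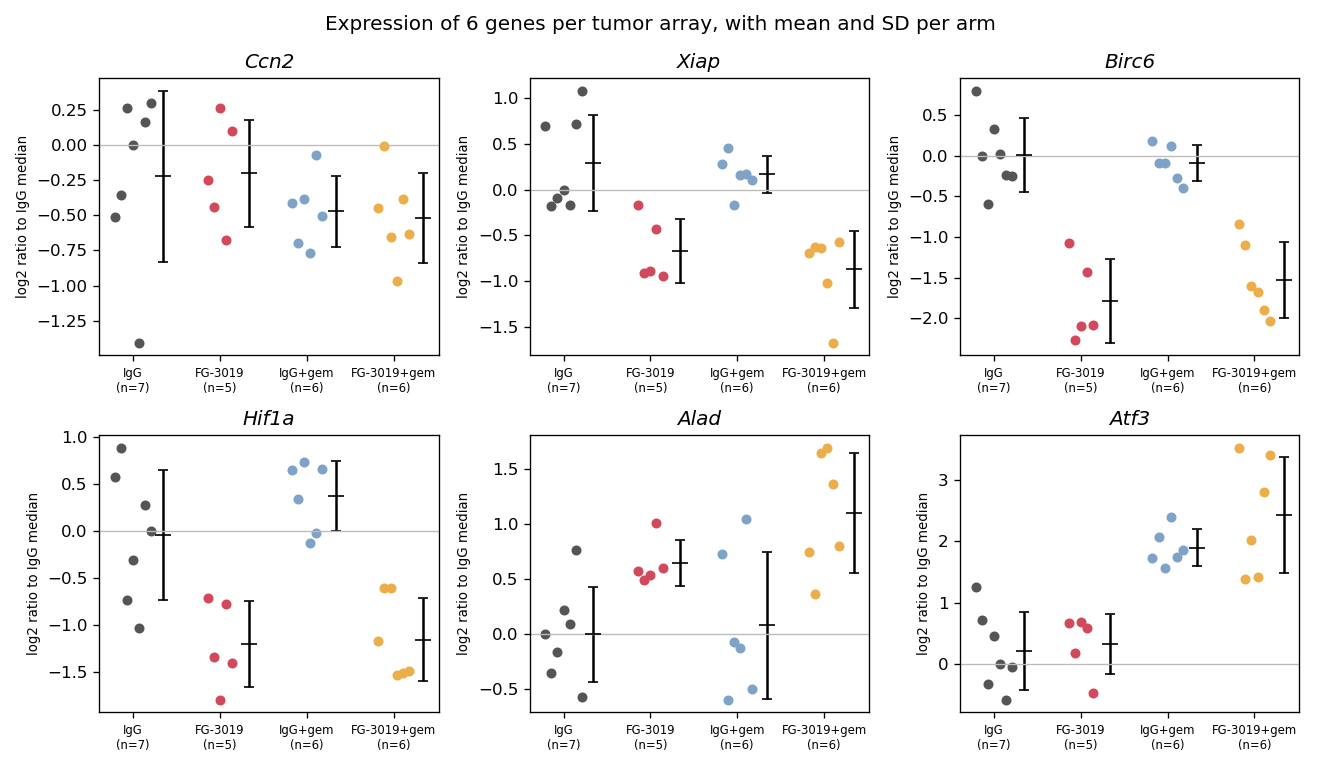
Log2 ratio to the IgG median (vertical axis) of 6 genes on each array, by arm (horizontal axis), with a bar at the mean and whiskers of 1 SD. Birc6 lay between −2.27 and −0.84 on all FG-3019 arrays and between −0.60 and 0.80 on all IgG antibody arrays, whereas Ccn2 overlapped between arms and Atf3 was higher in both gemcitabine arms.

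Lamc1 (−0.89, adjusted p = 0.017) and Nid1, a basement membrane linker (−0.92, adjusted p = 0.032), fell among 28 matrix glycoproteins and crosslinkers, whose median was −0.34. Mmp14 fell by 0.88 (adjusted p = 0.041) among matrix proteases, whose median was −0.27. Mitosis genes had a median of 0.35 with Aurkb at 0.61, ductal markers of 0.41 with Tff2 at 2.35 and Agr2 at 2.19, and B and plasma cell markers of 0.67 with Iglv1 at 1.85 and Pou2af1 at 1.40, and none of these members passed. All 5 lists were called by camera and had an adjusted p = 0.535 with an estimated correlation. The ductal median was 0.22 without IgG plus gemcitabine replicate 3 and 0.66 without FG-3019 plus gemcitabine replicate 5, and that of B and plasma cells was 0.39 without FG-3019 replicate 2. Without sex in the fit matrix glycoproteins (−0.04), matrix proteases (−0.12) and mitosis genes (0.145) were not called, and Nid1 (−0.61), Mmp14 (−0.55), Cacna2d1, Mansc1 and Frmd4b did not pass. With mouse number as a covariate the same 3 lists were not called, matrix proteases with a median of 0.19, and in females alone all but B and plasma cells (0.34) were. The count of 161 was 83 without FG-3019 plus gemcitabine replicate 5, 0 with mouse number as a covariate, 14 in females alone, 30 with the mean of all probe sets and 89 with a replicate block. With mouse number as a covariate the median change of the 152 lower genes went from −0.80 to −0.61 while the median SE went from 0.15 to 0.26, and all 152 stayed negative. They were picked on the same arrays for being lower, so their staying negative is no independent support.

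**Figure D2:**
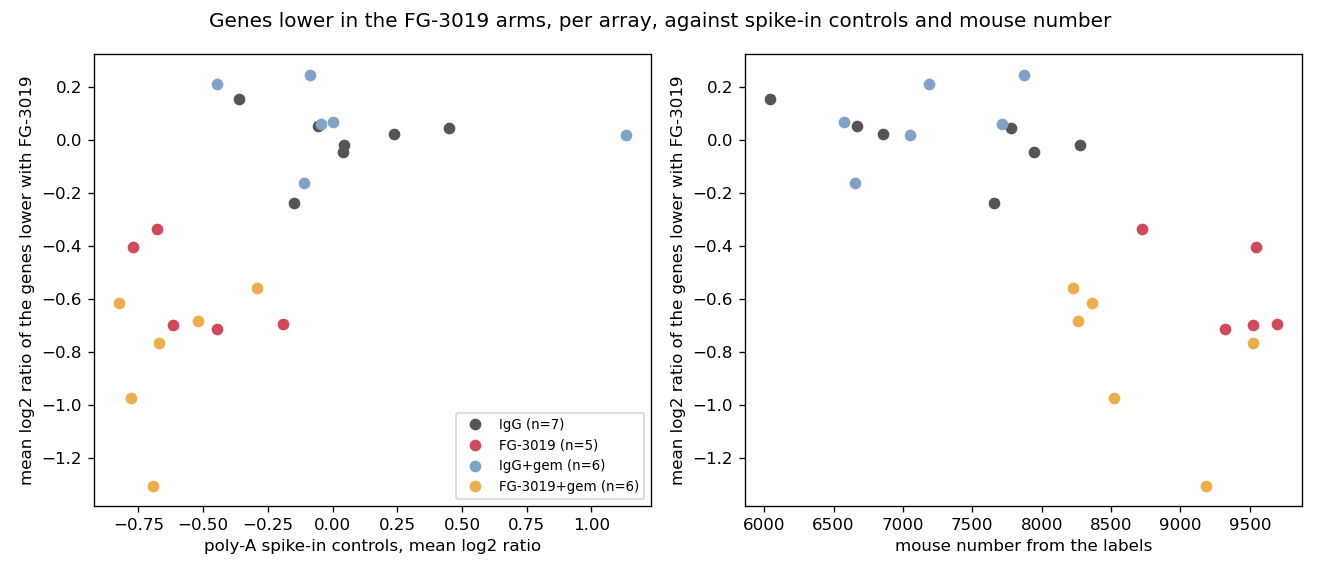
Mean log2 ratio of the 152 genes that were lower with FG-3019 (vertical axes) for each array, against the mean log2 ratio of the poly-A spike-ins (left) and mouse number (right), coloured by arm. The FG-3019 arrays lay between −1.30 and −0.34 on the vertical axis and the IgG antibody arrays between −0.24 and 0.25. The genes were picked on these same arrays for being lower with FG-3019, so a gap between the antibodies follows from the choice.

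The comparisons of FG-3019 with and without gemcitabine share no arrays, but 1 fit of all 24 arrays gave both the same sex term and the same variance of each gene, and the probe set of a gene was chosen over all arrays. Of the 12 genes lower without gemcitabine all 12 were negative with it, and 5 were called lower there too, where lists independent of each other would share 0.15. With only the compared arms in the fit no gene was called without gemcitabine, so no call was shared. Across all genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.29 and a Spearman rho of 0.25. For gemcitabine with and without FG-3019 they correlated with a Pearson r of −0.06 and a Spearman rho of −0.07.

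IgG plus gemcitabine against IgG asks what gemcitabine changed without the antibody. No gene passed in limma, and 557 had an unadjusted p under 0.05 where chance gives 620. The smallest p belonged to Atf3, a stress-induced transcription factor (1.72), Tnfrsf9 (1.73), the chemokine Cxcl1 (1.79), Mafg (0.44) and Rufy2 (0.61) among higher values, and to Septin3 (−0.48), Tnfsf8 (−1.44), Frmd4b (−0.72), Foxp2 (−0.68) and Map3k1 (−0.72) among lower ones, each with an adjusted p of 0.768 or more. Ccn2 was at −0.18 (SE 0.23) and Xiap at −0.10 (SE 0.23).

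By camera 12 lists shifted. Unfolded protein and heat shock genes were higher in 21 of 23, with a median of 0.27, and this call held with an estimated correlation (adjusted p = 0.040). Ddit3, a transcription factor of that response (0.77), and Chac1 (1.13) passed adjusted over the list alone, and Atf4 was at 0.45. Immediate early genes, which handling or ischaemia also raises, had a median of 0.39, with Atf3 and Jund (0.58) past the threshold adjusted over the list alone and an adjusted p = 0.082 with an estimated correlation. Inflammatory cytokines had a median of 0.64, with 4 of 25 past it, among them Cxcl2 (2.15), Tnf (1.74) and Nfkbia (0.91), and an adjusted p = 0.275 with an estimated correlation. Hypoxia and glycolysis genes had a median of 0.42, with Ero1a at 1.04. Acinar genes had a median of −1.86, Ctrb1 at −3.29 and Bhlha15 at −1.12, and islet genes of −1.24, Ins2 at −2.82. With an estimated correlation the adjusted p was 0.434 for hypoxia and islet genes and 0.441 for acinar genes. Without IgG replicate 4 the acinar median was −0.99 and the islet median −0.77, and without IgG replicate 2 the islet median was −0.79. The inflammatory median was 0.39 without IgG plus gemcitabine replicate 1, the hypoxia median 0.26 without IgG replicate 5 and the unfolded protein median 0.40 without IgG replicate 1. The inflammatory list was not called in females alone (0.35). Immune cell lists were called lower, B and plasma cells with a median of −0.64, MHC class II of −0.45 and T and NK cells of −0.09, with an adjusted p of 0.419, 0.434 and 0.780 with an estimated correlation. Without IgG replicate 2 the medians were −0.36 for B and plasma cells and −0.19 for MHC class II, and without IgG plus gemcitabine replicate 3 they were −0.36 and −0.30. That of MHC class II was −0.27 without IgG replicate 1 and −0.30 without IgG plus gemcitabine replicate 5. The T and NK cell call ended for 15 of 24 arrays left out, with medians from −0.17 without IgG plus gemcitabine replicate 1 to −0.05 without replicate 4.

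FG-3019 plus gemcitabine against FG-3019 asks what gemcitabine changed under the antibody. Atf3 rose by 2.14 (SE 0.40, adjusted p = 0.042), a 4.40-fold higher level, and 7 genes fell: Lrrfip1 (−1.52), Eif3c (−1.34, SE 0.19, adjusted p = 0.0052), Sp4 (−1.29), Heatr6 (−1.28), Hdlbp (−1.22), Rufy2 (−1.10) and Washc2 (−1.05). Pibf1 (0.87), Tnni1 (0.57), the immediate early gene Egr1 (1.76) and Zfp36, which destabilizes cytokine mRNAs (0.96), did not pass. Ccn2 was at −0.22 (SE 0.25) and Xiap at −0.16 (SE 0.25). Of the 8 lists called by camera, interferon-responsive genes had the smallest adjusted p, with 22 of 23 higher, a median of 1.03 and 7 past the threshold adjusted over the list alone, among them Irf7 (1.83), Oas1a (1.71) and Cxcl10 (1.61), and an adjusted p = 0.107 with an estimated correlation. Immediate early genes had 7 of 25 higher past it in the same way, with Jun at 1.40, and the same adjusted p = 0.107 with an estimated correlation. All 29 mitosis genes were lower, with a median of −0.45 and 0 past the threshold, Cdc20 at −0.77 and Foxm1 at −0.68, and an adjusted p = 0.671 with an estimated correlation. Islet genes had the largest median, 1.415 (adjusted p = 0.342 with an estimated correlation), and were called whichever array was left out. B and plasma cells (−0.69), muscle (−0.29) and T and NK cells (−0.18) were lower and p53 targets (0.11) higher, with an adjusted p of 0.342 or more with an estimated correlation. Without FG-3019 replicate 2 the calls of B and plasma cells and of T and NK cells ended, both at −0.11, and without FG-3019 plus gemcitabine replicate 3 (−0.61) or 6 (−0.49) that of B and plasma cells did. The muscle median was −0.155 without FG-3019 replicate 1 and −0.49 without replicate 4, and that of T and NK cells −0.275, −0.32 and −0.10 without FG-3019 replicate 3, 4 and 5 and −0.29 without FG-3019 plus gemcitabine replicate 4. The p53 target call ended without FG-3019 replicate 1 (0.14) or 4 (0.06) or FG-3019 plus gemcitabine replicate 1 (0.15), and the median was 0.18 without FG-3019 replicate 2 or 5 or FG-3019 plus gemcitabine replicate 4 or 6. That call also ended without sex in the fit (0.04). The count of 8 was 0 in females alone and moved by over 1.5 times for 16 of 24 arrays left out. It was 1 without FG-3019 replicate 4 or 5, 2 without IgG replicate 4 or 7, FG-3019 replicate 3, IgG plus gemcitabine replicate 1 or FG-3019 plus gemcitabine replicate 5 or 6, and 3 without FG-3019 replicate 1 or FG-3019 plus gemcitabine replicate 2. It was 4 without IgG replicate 6, FG-3019 replicate 2, IgG plus gemcitabine replicate 6 or FG-3019 plus gemcitabine replicate 3, and 5 without IgG replicate 5 or IgG plus gemcitabine replicate 3. Eif3c passed whichever array was left out, Atf3 passed in 5 of 24 cases, and Lrrfip1 did not pass without sex in the fit.

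Gemcitabine averaged over antibody had 1 gene past the threshold. The changes it averages, with and without FG-3019, did not run parallel across genes (Pearson r −0.06), and of 311 genes higher at an unadjusted p under 0.05 without FG-3019, 124 were positive with it, as 129 of 246 lower genes were negative. Atf3 rose by 1.93 (SE 0.28, adjusted p = 0.0090), a 3.80-fold higher level, and passed whichever array was left out. Cxcl1 (1.79), Egr1 (1.30), Nr2c2 (−0.51), Eif4ebp2 (−0.84) and Foxp2 (−0.54) had the next smallest p in each direction and did not pass, and Ccn2 was at −0.20 and Xiap at −0.13. Immediate early genes were higher in 22 of 25, with a median of 0.27 and 8 past the threshold adjusted over the list alone, Jun (1.00) and Zfp36 (0.67) among them, and this call held with an estimated correlation (adjusted p = 0.0080). Unfolded protein and heat shock genes had a median of 0.23, with Ddit3 at 0.50, and this call held too (adjusted p = 0.041), although the median was 0.13 without IgG plus gemcitabine replicate 3. This average contains IgG plus gemcitabine against IgG, so the 2 calls of this list are not separate support. The list was not called under the antibody. Its mean score was 0.006 with IgG and 0.344 with IgG plus gemcitabine, against 0.169 with FG-3019 and 0.23 with FG-3019 plus gemcitabine. Interferon-responsive genes had a median of 0.56, with 8 of 23 past the threshold adjusted over the list alone, Cxcl10 (1.45) and Irf7 (1.31) among them, and an adjusted p = 0.089 with an estimated correlation. B and plasma cell markers had a median of −0.71, with Ighm at −3.11 and Jchain at −2.26, and an adjusted p = 0.195 with an estimated correlation. T and NK cell markers had −0.17 (adjusted p = 0.289 with an estimated correlation), and −0.11 without FG-3019 replicate 2. The 20 genes that transport, activate or inactivate gemcitabine or are its targets had a median of 0.006 and a mean of 0.02 against a lower direction by camera, with Rrm2 at 0.45 and Dck, the kinase that activates the drug, at 0.19, and none passed. The count of 1 was 0 in females alone, with mouse number as a covariate, with a replicate block and without 4 arrays out of number order, and 2 without IgG plus gemcitabine replicate 1 or FG-3019 plus gemcitabine replicate 1.

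**Figure D3:**
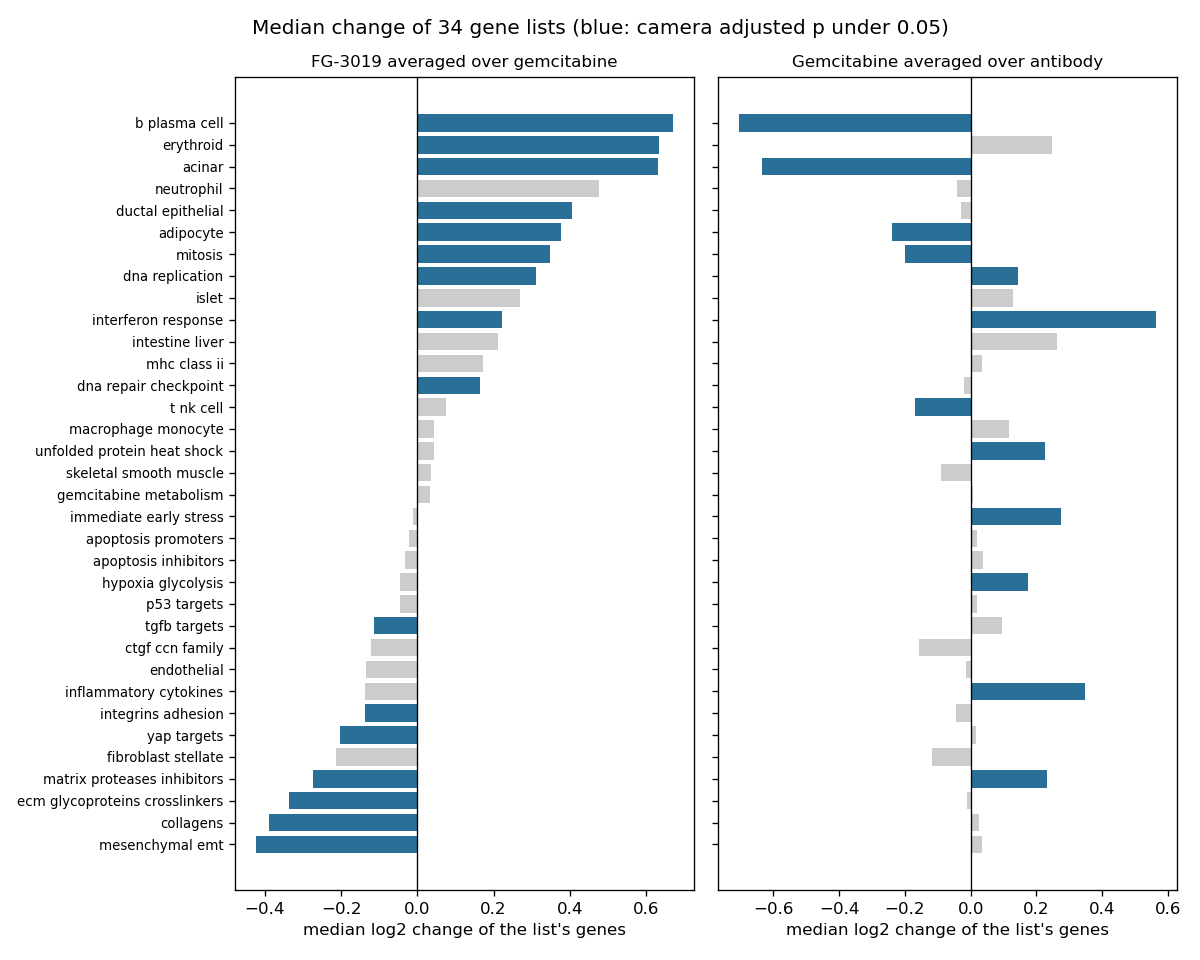
Median log2 change of the genes of each of 34 lists (horizontal axes) for FG-3019 averaged over gemcitabine (left) and gemcitabine averaged over antibody (right). Blue bars had an adjusted p under 0.05 by camera at a preset correlation of 0.01, and of these the immediate early and the unfolded protein and heat shock lists on the right held with an estimated correlation.

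FG-3019 plus gemcitabine against IgG compares both treatments with neither. It had 16 genes higher and 109 lower. Bpifb1, a secreted protein of mucosal epithelium, rose by 3.51 (SE 0.80, adjusted p = 0.030), Atf3 by 2.21 (SE 0.36, adjusted p = 0.0023), Jun by 1.49 (SE 0.29) and Fos by 1.29 (SE 0.30). Cyp2j5 (2.02), Lrr1 (1.64), Dusp8 (1.40), Alad (1.16), Mthfd2 (1.15) and Rad51c, a recombination protein (1.04), also rose. Cacna2d1 (−1.81), Lrrk1 (−1.65), Birc6 (−1.53), Utrn (−1.51), Eif4ebp2 (−1.46), Cygb (−1.42), Top2b (−1.40), Thrap3 (−1.32), Rbm25 (−1.32) and Sp4 (−1.28) fell, and so did Xiap (−1.18, SE 0.22, adjusted p = 0.0094). Ccn2 was at −0.32 (SE 0.23, adjusted p = 0.746). By camera 13 lists shifted. Immediate early genes had 4 of 25 higher past the threshold over all genes, Ier2 (1.00) among them, and an adjusted p = 0.247 with an estimated correlation. Interferon-responsive genes had a median of 1.02, with Cxcl10 at 1.75 and Irf7 at 1.51, and the same adjusted p = 0.247 with an estimated correlation. DNA replication genes had a median of 0.44, with 12 of 31 past the threshold adjusted over the list alone, Cdc6 (1.31) and Mcm10 (1.06) among them, and an adjusted p = 0.374 with an estimated correlation. Neither Cdc6 nor Mcm10 passed over all genes. DNA repair and checkpoint genes had a median of 0.16, with Blm at 0.59 and an adjusted p = 0.576 with an estimated correlation. Erythroid (0.885), intestine and liver (0.54) and islet genes (0.47) were called too, with an adjusted p of 0.576 or more with an estimated correlation. In females alone erythroid (0.08) and intestine and liver genes (−0.001) were not called, nor with mouse number as a covariate. Without sex in the fit erythroid genes (0.81) were not called. The erythroid call ended without FG-3019 plus gemcitabine replicate 4 (0.12) or IgG replicate 1 (0.81), and that of intestine and liver without IgG replicate 1 (0.37) or 2 (0.42) or FG-3019 plus gemcitabine replicate 4 (0.39), with 0.945 without replicate 5. The islet call ended without IgG replicate 3 (0.17) or 7 (0.15) or FG-3019 plus gemcitabine replicate 1 (0.42) or 3 (0.49), and the median was 0.735 without IgG replicate 2 and 0.77 without IgG replicate 4. The count of 125 was 46 without FG-3019 plus gemcitabine replicate 5, 0 in females alone, 4 with mouse number as a covariate and 27 with the mean of all probe sets. Of the 22 called genes named, 8 passed whichever array was left out, Atf3, Alad, Birc6, Utrn, Eif4ebp2, Thrap3, Sp4 and Xiap, whereas Rad51c passed in 4 of 24 cases. Cyp2j5, Fos, Alad, Rad51c, Cacna2d1 and Cygb did not pass without sex in the fit, and DNA repair genes were not called with mouse number as a covariate.

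The interaction asks whether the antibody effect differed with gemcitabine. It had 7 genes past the threshold, all negative: Lrrfip1 (−2.05, SE 0.36), Eif3c (−1.95, SE 0.24, adjusted p = 0.00070), Hdlbp (−1.72, SE 0.29), Rufy2 (−1.71, SE 0.22), Heatr6 (−1.64, SE 0.29), Pdap1 (−1.50) and Scaf4 (−0.89), the last pair outside the naming rule and added after their values were seen. Pibf1 (1.06), Fgl2 (2.43) and Etnk1 (1.95) had the smallest p among positive values and did not pass, and Ccn2 (−0.04, SE 0.33) and Xiap (−0.06, SE 0.33) did not either. By camera 8 lists shifted. Islet genes had a median of 2.80, with Scg2 (3.92) and Isl1 (1.56) past the threshold adjusted over the list alone, and acinar genes of 2.64, with Reg1 at 3.17 and Gp2 at 3.80, though the acinar median was 1.34 without IgG replicate 4. Interferon-responsive genes had a median of 0.87, with Ifih1 at 0.81 and Irf7 at 1.05. With an estimated correlation the adjusted p was 0.530 for islet and interferon genes and 0.538 for acinar genes. The count of 7 was 0 in females alone and moved by over 1.5 times for 18 of 24 arrays left out. It was 13 without IgG replicate 1, 4 without FG-3019 replicate 2 or IgG plus gemcitabine replicate 3, and 3 without FG-3019 plus gemcitabine replicate 6. It was 2 without IgG replicate 2, 3, 4, 5 or 6, FG-3019 replicate 1, 4 or 5, IgG plus gemcitabine replicate 1, 2 or 6, or FG-3019 plus gemcitabine replicate 2, 3 or 4. Eif3c and Rufy2 passed whichever array was left out, and Lrrfip1 did not pass without sex in the fit.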

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

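Every test of a technical or biological explanation in this part was chosen after related values had been seen, and the test on other probe sets was redefined after its first values were seen, whereas the tests against other splits of the arrays were set before.

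The genes lower with FG-3019 are the first pattern weighed. Removing each array's trend with gene span left 114 of the 152 genes called, with a median going from −0.80 to −0.77. This argues only against a trend common to all genes of similar span as the whole cause. The genes were picked on the same arrays, and an effect on a part of the long transcripts would survive this removal. Such an effect stays open, since these genes span a median of 69189 bases against 19747 for the others. Slopes with mouse number within arms give −0.166 of a difference of −0.736 between antibodies, a share of 0.225. The 95% interval of that part ran from −0.388, a share of 0.526, to 0.056 in the other direction. A trend with mouse number thus stays open. Slopes within arms do not test a step between the antibodies, whose mouse numbers did not overlap with or without gemcitabine. A labelling or hybridization batch cannot be told apart from the antibody, since no batch is named and the poly-A spike-ins differed by −0.639, the hybridization spike-ins by −0.259 and the Gapdh 3′ to 5′ ratio by −0.111 between antibodies, although that ratio differed by −0.049 without gemcitabine (exact p = 0.184) and that of Actb by −0.051 (permutation p = 0.109). A lower level of the whole transcripts, a biological explanation, stays open as well. Other probe sets of the same genes were measured in arms not used to pick the genes. In 7 of 8 versions they fell by 0.18 to 0.418 of the picked ones, and in 6 of 8 the 95% interval lay under 0.5. In 1 version on 28 genes the ratio was 0.699 (95% interval 0.084 to 2.07). The intervals of these ratios come from resampling genes, not mice. They leave out the spread between mice and treat genes that vary together as independent, and the 8 versions share arrays and genes. The picked probe set was the most variable of its gene, which can lower this ratio, so the ratio does not decide the question.

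Counts of genes were set against other splits of the same arrays into groups of the same sizes, 100 splits per comparison with the real one. Only the real split gave as many genes for FG-3019 against IgG (12, highest other 6) and for the antibody average (161, highest other 56). The same held for FG-3019 plus gemcitabine against IgG plus gemcitabine (167, highest other 50) and against FG-3019 (8, highest other 1). With 100 splits and no correction over the 8 contrasts, this argues against chance for these counts but does not exclude it. The count of 12 was as low as 5 with 1 array left out, under the highest other split. The count of 8 was as low as 1 with 1 array left out, no more than the highest other split, and 0 in females alone. For the interaction the real split was also the only one as large (7, highest other 4). Its splits mixed all 24 arrays and removed both treatment effects too, so they do not test an interaction. With 1 array left out the interaction count was as low as 2. For FG-3019 plus gemcitabine against IgG 2 of 100 splits gave at least 125 genes, the real one included, and for the gemcitabine average 3 gave at least 1, but the highest other gave 332 and 9. What gave counts that far above the real ones was not tested. For IgG plus gemcitabine against IgG all 100 splits gave at least 0 genes, and the highest gave 11. These splits do not separate the antibody from a batch that follows it.

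Counts of lists called by camera were not beyond other splits in any comparison. The real and highest other counts were 19 and 21 for FG-3019 against IgG (6 of 100 splits as large), 12 and 22 for IgG plus gemcitabine against IgG (44), 15 and 19 for FG-3019 plus gemcitabine against IgG plus gemcitabine (12), 8 and 20 against FG-3019 (61), 13 and 19 against IgG (45), 16 and 21 for the antibody average (14), 12 and 18 for the gemcitabine average (32) and 8 and 19 for the interaction (75). Median counts of the other splits lay between 8 and 12, so list calls at the preset correlation come about by chance in these tumors.

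Acinar and islet genes are the second pattern. Leaving out 1 array never turned the acinar shift of FG-3019 plus gemcitabine against IgG plus gemcitabine, the lowest median being 1.431 without FG-3019 plus gemcitabine replicate 3, which argues against a single array for that comparison, whereas the median of IgG plus gemcitabine against IgG went from −1.86 to −0.99 without IgG replicate 4. With mouse number as a covariate the acinar median with gemcitabine was 0.305 and not called. Differing amounts of normal pancreas stay open, since acinar and islet scores within arms correlated at r = 0.439 (permutation p = 0.117, rho = 0.327, permutation p = 0.186, 24 arrays), and r was 0.172 without the 2 arrays farthest in the acinar score. The third pattern is the interferon-responsive list under gemcitabine, where 2 of 3 immune cell lists had a median at or below 0 (T and NK cells −0.17, B and plasma cells −0.71, macrophages 0.12). These medians lend no weight to a higher share of all immune cells. They cannot exclude it either, since neither lower list held with an estimated correlation, and a change in 1 cell type stays open.

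Antibody effects that differed between mice with and without gemcitabine, by the interaction, were those of Lrrfip1 (−2.05), Eif3c (−1.95), Hdlbp (−1.72), Rufy2 (−1.71), Heatr6 (−1.64), Pdap1 (−1.50) and Scaf4 (−0.89). By camera they were the islet (2.80), acinar (2.64), interferon (0.87), MHC class II (0.83), p53 target (0.065), muscle (−0.33), hypoxia and glycolysis (−0.42) and mitosis (−0.45) lists, as medians, none of them called with an estimated correlation. The acinar median was 1.34 without IgG replicate 4, that of MHC class II 0.44 without IgG replicate 2 and that of muscle −0.18 without FG-3019 replicate 1, and the p53 target list was called for 15 of 24 arrays left out, with medians from 0.042 to 0.223, and not without sex in the fit.

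Single arrays stood apart from their arm, by a gap over the arm's whole range, in 49 of 628 tested groups of 5 to 7 arrays, where chance gives about 31.4. IgG plus gemcitabine replicate 1 was involved most often, in 8: it was highest in the hybridization spike-ins (0.879), the poly-A spike-ins (0.716), the inflammatory cytokine list (0.731), the intestine and liver list (0.647), Cxcl2 (0.705), Cyp2j5 (0.667), Cxcl1 (0.642) and Dusp8 (0.638). In the same arm replicate 3 was lowest in Muc1 (0.739), Fos (0.708), Map3k1 (0.706), Krt19 (0.671), the ductal list (0.661) and Frmd4b (0.644) and highest in Mafg (0.637). Replicate 4 was highest in the acinar list (0.858) and Gp2 (0.692), replicate 2 was lowest in Tnfsf8 (0.651) and highest in Tnni1 (0.639), replicate 5 was lowest in Jun (0.768), and replicate 6 was lowest in Sos1 (0.756) and highest in Isl1 (0.737). In the FG-3019 plus gemcitabine arm replicate 5 was lowest in Hdlbp (0.757), Secisbp2l (0.734), Utrn (0.670) and Top2b (0.666) and highest in the adipocyte list (0.668). Replicate 4 was highest in the erythroid (0.865) and intestine and liver (0.684) lists and lowest in Col6a3 (0.756), replicate 3 was lowest in Map3k1 (0.678) and Muc1 (0.671), and replicate 6 was lowest in Jchain (0.663) and Iglv1 (0.642). In the FG-3019 arm replicate 4 was highest in Lrrfip1 (0.807), Alad (0.785) and the unfolded protein list (0.767) and lowest in the mesenchymal list (0.710). Replicate 2 was highest in Bhlha15 (0.903) and Ier2 (0.766), and replicate 5 was lowest in Chgb (0.763) and Septin3 (0.720). In the IgG arm replicate 5 was highest in Bhlha15 (0.699) and lowest in Nid1 (0.743) and the YAP target list (0.668). Replicate 2 was highest in the T and NK cell list (0.713), replicate 1 in Cfap298 (0.647) and replicate 4 in Cyp2j5 (0.599), and replicate 3 was lowest in Ube3a (0.639).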

How the results depend on the processing

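Alternatives with a gene span trend removed, without 2 doubted arrays (IgG replicate 4, highest in acinar genes, and IgG plus gemcitabine replicate 1, highest in spike-ins) and without the 2 arrays with Xist out of place were chosen after seeing the data. The values have no absolute signal, so what signal over background limits is unknown. Across 184 gene results, 6504 of 7473 values under alternatives kept direction and side of the threshold, 873 lost the call, 55 gained it and 41 turned sign, none of them from a called gene. Results not called in the main fit counted as kept when they stayed uncalled, and only called genes could lose a call. The share of called genes that lost it is therefore higher than these totals show. Of the kept values 3933 came from leaving out 1 array. Of 4516 values of lists 3828 kept both, 666 lost the call and 22 turned direction, 10 of them from called lists. Of 103 list calls 40 ended or turned without sex, 35 in females, 20 in both and 45 with mouse number, and 3 held with an estimated correlation and 3 with fry. The cause of each change below was not tested, except that females alone and the compared arms alone use fewer arrays.

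Counts of genes changed are given in the order FG-3019 against IgG (12), FG-3019 plus gemcitabine against IgG plus gemcitabine (167), against FG-3019 (8), against IgG (125), the antibody average (161), the gemcitabine average (1) and the interaction (7), where they moved over 1.5 times. Females alone gave 1, 35, 0, 0, 14, 0 and 0. The mean of all probe sets gave 2, 34, 1, 27 and 30, with 1 for the interaction. Mouse number as a covariate gave 0, 10, 2, 4, 0 and 0 for the first 6. The replicate block gave 5 for the first, 1 against FG-3019, 76 against IgG, 89, 0 and 2. Quantile normalization gave 19, 89, 62 against IgG, 2 for gemcitabine and 3 for the interaction. Array weights gave 28 and, against FG-3019, 24. The compared arms alone gave 0, 1 against FG-3019 and 54 against IgG. The more variable genes gave 7 and, for gemcitabine, 2. Without sex gemcitabine gave 4. Without 4 arrays out of number order the counts were 1 against FG-3019, 69 against IgG and 0 for gemcitabine. Without the 2 doubted arrays they were 2 against FG-3019, 2 for gemcitabine and 2 for the interaction, and without the 2 arrays with Xist out of place 2 against FG-3019. IgG plus gemcitabine against IgG stayed at 0 under every alternative run. Leaving out 1 array gave 5 to 21, 75 to 236, 1 to 10, 46 to 136, 83 to 190, 1 to 2 and 2 to 13. Lower genes made up 97.8% of the calls for FG-3019 plus gemcitabine against IgG plus gemcitabine after quantile normalization, 90.9% with arrays centred on their median and 94% as deposited.

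Replicate numbers do not pair the mice: arrays with the same number correlated at a median of 0.02 in their deviations from the arm means (33 pairs, −0.31 to 0.37), others at −0.01, so the replicate block shares a number alone.

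Ccn2 turned positive for FG-3019 against IgG without sex (0.021), with the replicate block (0.031) and without FG-3019 replicate 4 (−0.219 to 0.015 over arrays left out), for FG-3019 plus gemcitabine against IgG plus gemcitabine with array weights (0.012) and in females (0.11), and for the interaction with array weights (0.17), in females (0.36), without the span trend (0.02), after quantile normalization (0.16), without the 4 arrays out of order (0.027) and for 8 arrays left out (−0.156 to 0.132). Xiap turned positive for FG-3019 plus gemcitabine against FG-3019 in females and with the compared arms alone (both 0.037), for IgG plus gemcitabine against IgG with the replicate block (0.016), without the 4 arrays out of order (0.023), without the 2 with Xist out of place (0.010) and for 4 arrays left out (−0.184 to 0.018), and for the interaction in females (0.092), with the mean of probe sets (0.156), after quantile normalization (0.089), without the 2 doubted arrays (0.038) and for 6 arrays left out (−0.201 to 0.086). For the antibody average Ccn1 turned with mouse number (0.27) and without sex (0.014), Ccn4 without sex (0.11), and Iglv1 without probe sets matching several transcripts (−0.12).

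Lists whose camera direction turned, with their medians, were for the antibody average the CCN family in females (−0.073), with mouse number (0.27), without sex (0.11), without the 2 doubted arrays (−0.10) and for 5 arrays left out (−0.212 to −0.063), apoptosis inhibitors (−0.024) and erythroid genes (0.006) in females, and with mouse number acinar (−0.99), integrin (0.077), interferon (−0.32) and TGF-beta target (−0.046) genes. For FG-3019 against IgG they were matrix proteases (0.25) and TGF-beta targets (0.087) with mouse number and mesenchymal genes (0.054) without sex, and for FG-3019 plus gemcitabine against IgG plus gemcitabine DNA replication (−0.11) and erythroid genes (0.008) in females. Gemcitabine metabolism turned for gemcitabine with the more variable genes (0.02) and without sex (−0.031). Among called lists and apart from arrays left out, the median alone turned for the antibody average in matrix proteases (0.191) with mouse number, for FG-3019 against IgG without sex in matrix glycoproteins (0.024), hypoxia (−0.01), p53 (0.002) and TGF-beta targets (0.001), for gemcitabine without sex in matrix proteases (−0.004), and in females for FG-3019 plus gemcitabine against IgG in inflammatory (−0.025) and intestine and liver genes (−0.001).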

Other observations

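Other lists were called by camera for FG-3019 averaged over gemcitabine, and none held with an estimated correlation. DNA replication genes had a median log2 change of 0.31, DNA repair genes 0.16, adipocyte genes 0.38 and erythroid genes 0.63, while collagens had −0.39, mesenchymal genes −0.42, YAP targets −0.20, integrins −0.14 and TGF-beta targets −0.11, each with an adjusted p = 0.535 with an estimated correlation. Interferon-responsive genes (0.22, adjusted p = 0.688 with an estimated correlation) and acinar genes (0.63, adjusted p = 0.710 with an estimated correlation) were called too. Without FG-3019 plus gemcitabine replicate 4 the erythroid median was 0.02, and without FG-3019 plus gemcitabine replicate 5 the adipocyte median was 0.09, neither of them called, while without FG-3019 replicate 1 the adipocyte median was 0.24. Of 24 arrays left out in turn, the call ended for 10 in the erythroid list, 12 in the acinar and YAP target lists, 7 in integrins, 6 in interferon-responsive genes and 5 in TGF-beta targets. The acinar median lay between 0.29 without IgG replicate 2 and 1.37 without IgG replicate 4, with 0.34 without IgG replicate 7 and 1.00 without FG-3019 plus gemcitabine replicate 4. The interferon median was −0.008 without IgG plus gemcitabine replicate 2, 0.38 without replicate 3 and 0.13 without replicate 5 of that arm, 0.126 without FG-3019 plus gemcitabine replicate 5, and 0.139 and 0.137 without IgG replicates 4 and 7. The median of TGF-beta targets was −0.18 without FG-3019 plus gemcitabine replicate 5. Without sex in the fit only the DNA replication (0.19), interferon (0.22) and acinar (0.61) lists were called of these, with collagens at −0.05, mesenchymal genes at −0.16 and YAP targets at −0.03. In females alone collagens (−0.45), mesenchymal genes (−0.38), TGF-beta targets (−0.19), DNA replication (0.175) and acinar genes (1.125) were called. With mouse number as a covariate only DNA replication genes kept their call, and the interferon list was called lower (−0.32). Not called were neutrophil (0.48), islet (0.27), intestine and liver (0.21), MHC class II (0.17), T and NK cell (0.08), macrophage (0.045), unfolded protein (0.04), muscle (0.035), gemcitabine metabolism (0.03), immediate early (−0.01), apoptosis inhibitor (−0.03), hypoxia (−0.045), p53 target (−0.046), endothelial (−0.13), inflammatory (−0.14) and fibroblast and stellate cell (−0.21) genes. Apoptosis promoters were not called either, with a median of −0.02, a mean of 0.03 and a higher direction by camera.

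For gemcitabine averaged over antibody, matrix proteases had a median of 0.23 (adjusted p = 0.296 with an estimated correlation). DNA replication genes (0.145), hypoxia genes (0.175), mitosis genes (−0.20) and adipocyte genes (−0.24) had an adjusted p = 0.693 with an estimated correlation, and acinar genes (−0.63) an adjusted p = 0.998. Without IgG replicate 5 the median was 0.115 for matrix proteases and 0.049 for hypoxia genes, neither of them called, and −0.08 for mitosis genes, which had −0.30 without IgG replicate 6. The DNA replication call ended without IgG plus gemcitabine replicate 2, at 0.105. The acinar call ended for 14 of 24 arrays left out, with medians of −0.287 without IgG replicate 4, −0.336 without IgG replicate 5, −0.341 without FG-3019 plus gemcitabine replicate 1 and −0.391 without FG-3019 replicate 3. The adipocyte call ended for 16, with medians of −0.39 without IgG replicate 1, −0.14 without FG-3019 replicate 1 and −0.158 without FG-3019 plus gemcitabine replicate 3. Without sex in the fit matrix proteases (−0.004), mitosis (−0.04) and adipocyte genes (−0.05) were not called, in females alone mitosis (−0.02) and acinar genes (−0.50) were not, and with mouse number as a covariate acinar (−0.14) and adipocyte genes (−0.17) were not. Inflammatory cytokines had a median of 0.35, with an adjusted p = 0.195 with an estimated correlation and 4 of 25 genes past the threshold adjusted over the list alone. Lists not called whose median, mean and camera direction differed in sign were DNA repair (−0.02, 0.06, higher), matrix glycoproteins (−0.01, 0.02, higher), the CCN family (−0.16, 0.01, higher), integrins (−0.04, 0.003, lower), mesenchymal genes (0.04, −0.004, lower), MHC class II (0.035, −0.12, lower) and YAP targets (0.02, 0.02, lower).

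The remaining lists called by camera in comparisons of 2 arms, none of them held with an estimated correlation, follow with the number of 24 arrays whose absence ended the call. For FG-3019 against IgG they were DNA repair (0.17, 5), hypoxia (0.165, 5), matrix protease (−0.28, 4), mesenchymal (−0.34, 2), p53 target (−0.07, 8), TGF-beta target (−0.10, 10) and unfolded protein genes (0.11, 2). None of these was called without sex in the fit, where mesenchymal genes had 0.05, or with mouse number as a covariate, where matrix proteases had 0.25. In females alone p53 and TGF-beta targets were not called. Over arrays left out the median ran from 0.059 to 0.294 for hypoxia and from −0.137 to −0.019 for p53 targets. IgG plus gemcitabine against IgG had DNA replication (0.33, 0), interferon (0.20, 5) and matrix protease genes (0.32, 1). Over arrays left out the median ran from 0.168 to 0.404 for DNA replication and from 0.143 to 0.392 for interferon genes. In females alone interferon (0.09) and matrix protease genes (0.26) were not called. FG-3019 plus gemcitabine against IgG plus gemcitabine had DNA repair (0.18, 3), DNA replication (0.26, 3), matrix glycoprotein (−0.35, 2), hypoxia (−0.23, 6), integrin (−0.23, 3), interferon (0.575, 0) and YAP target genes (−0.43, 3). None of these was called with mouse number as a covariate, where interferon genes had 0.11 and integrins −0.006. Without sex in the fit only hypoxia and interferon genes were called, with matrix glycoproteins at −0.04. In females alone only interferon genes were, with DNA replication at −0.11. Against IgG there were collagens (−0.39, 5), ductal (0.34, 3), matrix glycoprotein (−0.32, 1), inflammatory (0.26, 0), mesenchymal (−0.47, 1) and unfolded protein genes (0.15, 0). Collagens and mesenchymal genes were not called without sex in the fit or with mouse number as a covariate, nor matrix glycoproteins with the latter. The inflammatory list was not called in females alone (−0.025), and its median ran from 0.142 to 0.556 over arrays left out.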
